A study of Mus musculus with 32 samples.

How the data were processed

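Mesenteric arteries were dissected free of perivascular fat and veins, and 1 µg of RNA per mouse was used for small RNA libraries with the TruSeq small RNA kit, per the labels' protocols. The submitters' processing notes name bcl2fastq 1.8.4, FastQC, STAR 2.3.1, R 3.2.3 and edgeR 3.6.8, without the role of each. The genome build, the miRNA annotation, the trimming and any filter are not given in the sources used here.

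The deposited table holds 1 normalized signal per miRNA and library, made by the authors. The values of each library were whole multiples of its smallest value above 0 (100% of values, within 0.001), so that they behave as read counts divided by a library size. The value of 1 read ranged from 0.0178 to 0.48, and the normalization factor implied by the deposited signal ranged from 0.295 to 1.90. Factors computed by the TMM method from the recovered reads were 0.86 to 1.24 times these. Because the factor is set by the authors and miR-143-3p and miR-10b-5p take most reads, a change in these abundant miRNAs and a change in the scaling of a library are hard to separate, and the precision of low miRNAs depends on the depth of each library.

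Groups were taken from the genotype and time in the labels. Of 32 labelled samples, 30 have a column in the table. The animal numbers in the labels do not repeat, so no pairing was used, although 1 pair of libraries under different numbers held near-identical counts. All libraries were compared with each other by chi-square of the recovered reads. miRNAs that share reads with a near-identical copy are uncertain: miR-486-5p was listed in 2 rows, miR-1h-5p_250 and miR-n3 had identical reads, and miR-28a-5p and miR-28c, miR-299a and miR-299b, miR-374b-5p and miR-374c-5p, miR-21b and miR-21c, and miR-1843a-5p and miR-1843b-5p were nearly so.

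miRNAs with a value of at least 1 in at least 8 libraries were tested (354 of 870, holding 99.99% of the reads). This filter stands for 3 to 57 reads, depending on the library. The main test was limma 3.58.1 (R 4.3.3) with an intensity trend on log2(value + 1), with 4 group means in 1 fit, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Folds are on this log2(value + 1) scale, which understates changes of low miRNAs. limma p-values measure the spread between libraries, taken as separate mice. Of 25 miRNA lists, the 21 with at least 3 tested members were tested with camera at a correlation of 0.01, with an estimated correlation and with fry as alternatives. A list takes every arm and copy of the miRNAs it names, so the same miRNA can count as several members. The groups, tests, lists and the alternatives named first below were fixed before the data were examined.

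miRNAs were named by a rule: for the genotype comparisons and their interaction up to 12 called miRNAs per direction with the largest change, for the time and averaged comparisons up to 6, where fewer than 6 passed those with the smallest p until 6 could be named, up to 4 members of a list with the smallest p, and the 5 most abundant miRNAs. The text gives a part of those the rule allows.

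Alternatives were pseudocounts of 0.5 and 5, no filter and a filter at 10, median-ratio, TMM and quantile scaling, robust empirical Bayes, array weights, edgeR 4.0.16 (quasi-likelihood) on the recovered reads, fits of only the groups compared, the range of animal number as a term at long term, and leaving out each library. Added after the data were seen were DESeq2 1.42.0, scaling to the total of all miRNA reads, reads thinned to the smallest effective library, the log2 of the reads as a term, and fits without the near-identical pair, without libraries under 5000000 reads, the range of animal number as a term at short term, without 2 libraries with high miR-200, or within ranges of animal number. Single library measures were compared with exact permutation tests. Precursor positions come from GENCODE M21 (GRCm38), matched by name. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

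The steps were tested on simulated data with reads drawn for the 870 miRNAs at their observed means, dispersions and depths, with 200 miRNAs changed, in 3 runs per comparison. For the short-term genotype comparison, with 354 miRNAs tested, limma found 4.71% of 1.5-fold, 39.5% of 2-fold and 90.2% of 4-fold changes, and for the long-term comparison, also with 354 tested, 15.8%, 41.9% and 89.0%. For the interaction, with 355 tested, it found 0% of 1.5-fold, 10.2% of 2-fold and 56.4% of 4-fold changes. Of the calls 1.65%, 6.45% and 3.57% were false in these 3 comparisons. The rates found apply with 200 of 870 miRNAs changed. Where fewer change, the Benjamini-Hochberg threshold is stricter, so these rates overstate how often a change would be found. The simulated miRNAs were drawn independently, with known scaling and without a near-identical pair or ranges of animal number. With no change simulated, limma made 2 calls in the 3 runs at short term and 0 at long term.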

Results

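Small RNA libraries were sequenced from the mesenteric arteries of male mice that overexpress endothelin-1, a vasoconstrictor peptide, in the endothelium after tamoxifen (ieET-1), and of control mice that carry the tamoxifen-inducible Cre recombinase alone (ieCre). Mice aged 10 to 12 weeks received tamoxifen for 5 days and were killed 16 days later (short term) or 3 months later (long term). Values for 870 mature miRNAs were analysed in 30 libraries, each labelled with a different animal number: 7 ieCre and 8 ieET-1 mice at short term, and 7 ieCre and 8 ieET-1 mice at long term. A further 2 ieCre mice of the labels, 1 at each time, were not analysed here. The recovered miRNA reads ranged from 1820000 to 35500000 per library. Their mean was 14300000 ± 11700000 (SD, n = 7) in ieCre short term, 24600000 ± 7760000 (n = 8) in ieET-1 short term, 11100000 ± 6610000 (n = 7) in ieCre long term and 15300000 ± 10100000 (n = 8) in ieET-1 long term.

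miR-143-3p, a miRNA abundant in vascular smooth muscle, took 45.5% of the reads on average over the 30 libraries, and miR-10b-5p, which lies among the Hoxd genes, took 20.3%. miR-10a-5p followed with 5.39%, and the erythroid and muscle miRNA miR-486-5p was listed in 2 rows of 3.92% each. These 2 rows had a Pearson correlation of 1 across the libraries, so their reads were shared between near-identical copies and are counted in both.

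Libraries of different genotype label shared nearly all of their counts in 1 case. The library labelled ieCre short term 8, with 31655543 reads, and the library labelled ieET-1 short term 258, with 30080771, had a Pearson correlation of 0.9999 on the log2 scale, against at most 0.9942 for any other of the 435 pairs. Over 537 miRNAs with at least 10 reads in the pair, 381 had more reads in library 8, 156 had equal reads and 0 had more reads in library 258. The chi-square per degree of freedom between them was 19.6, against 209 for the next closest pair. The short-term groups of 7 and 8 libraries may therefore hold fewer separate mice than their labels state. Both libraries were kept under their labels, since the files do not show which label the counts belong to, and the limma and edgeR counts of each comparison were also computed without both.

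**Figure D1:**
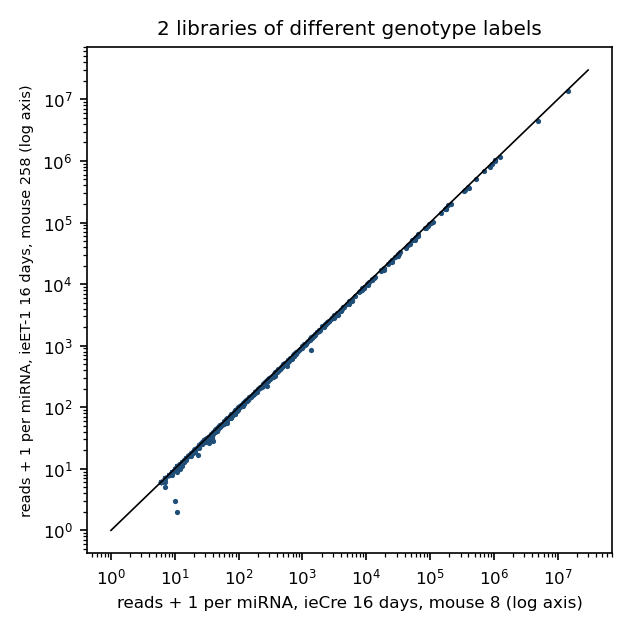
Reads per miRNA (plus 1, log axes) in the library labelled ieCre short term 8 (x axis) and in the library labelled ieET-1 short term 258 (y axis); each point is 1 of 537 miRNAs and the line marks equal reads. No point lies above the line.

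The mice also fell into ranges of animal number in the labels. At short term, 8 mice were numbered below 1000 and 7 at 8000 or above, with both genotypes in each range, and limma called 89 miRNAs different between these ranges (32 higher and 57 lower in the higher numbers; adjusted p below 0.05). That count was 63 without the near-identical pair. At long term, 9 mice in the 8000s and 6 in the 9000s differed in 5 miRNAs, or 26 with genotype as a term. No sequencing date or batch is given in the labels used here.

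The first question was whether endothelin-1 overexpression changed arterial miRNAs 16 days after tamoxifen. No miRNA passed the threshold. The lowest p among higher miRNAs belonged to miR-3968, 1.72-fold higher in ieET-1 mice (0.79 ± 0.32 on the log2 scale, SE), and the lowest among lower ones to miR-183-5p, at 59.5 ± 63.8 against 170 ± 182, 0.401-fold (normalized values, mean ± SD). Next in the higher direction came miR-143-5p (1.37-fold), miR-423-3p (1.77-fold) and miR-1964-3p (1.35-fold), and in the lower direction miR-154-5p (0.693-fold), miR-301b-3p (0.677-fold), miR-18a-5p (0.505-fold) and miR-450b-5p (0.785-fold). None of these passed, with an adjusted p of 0.99 each in limma.

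Of 354 miRNAs tested with limma at short term, 0 were called, 9 had an unadjusted p below 0.05 where chance gives 17.7, and edgeR on the recovered reads also called 0, with 9 at an unadjusted p below 0.05. DESeq2 called 0, with 13. The 95% interval of the fold change lay within 2-fold in either direction for 276 miRNAs (78.0%). This count, with the near-identical pair included, and those of the same kind below are on the log2(value + 1) scale. That scale understates changes of low miRNAs. Among the miRNA lists, the smooth muscle cluster of miR-143 and miR-145 had 4 of 5 members above 0 and a median of 0.34 on the log2 scale (camera adjusted p = 0.078, or 0.13 with an estimated correlation). The endothelial list, with miR-126, miR-221 and miR-222, had a median of 0.04 over 5 members (camera adjusted p = 0.954). The list of miRNAs reported to regulate endothelin-1 mRNA names 5 miRNAs and takes every arm of each. It had 6 of 9 tested members above 0 and a median of 0.11 (camera adjusted p = 0.476). The near-identical libraries lie on the 2 sides of this comparison, and without both of them limma called 0 miRNAs with 12 at an unadjusted p below 0.05, and edgeR 0 with 14. Within ranges of animal number, limma called 0 miRNAs among the 8 mice below 1000, with 34 at an unadjusted p below 0.05, and 0 among the 7 at 8000 or above, with 26. Both of these counts lie above the 17.7 that chance gives, unlike the 9 over all mice, whose fit held no term for the ranges. miR-196b-5p, 1.42-fold over all mice without passing, had a log2 change of -0.089 among the mice below 1000.

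The second comparison asked the same of mice 3 months after tamoxifen. Again no miRNA passed. miR-194-5p, a miRNA abundant in intestinal and other epithelia, had the smallest p, 2.04-fold higher in ieET-1 mice (1.03 ± 0.33 on the log2 scale, SE). miR-221-5p, of the endothelial list, was at 2.54 ± 2.22 against 7.01 ± 4.02 (0.446-fold), miR-19a-3p of the miR-17/92 cluster at 3.28 ± 1.70 against 6.63 ± 2.55 (0.538-fold) and the abundant miR-10b-5p at 219000 ± 75910 against 366600 ± 107600 (0.586-fold). Others named by the same rule were miR-872-3p (1.67-fold), miR-339-3p (1.58-fold) and miR-138-5p (2.37-fold), and miR-27a-5p (0.594-fold) and miR-3068-3p (0.707-fold), each with an adjusted p of 0.688 in limma.

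At long term limma called 0 of 354 miRNAs, with 20 at an unadjusted p below 0.05 against 17.7 by chance, edgeR called 0 with 27 and DESeq2 0 with 25. The 95% interval lay within 2-fold for 273 miRNAs (77.1%). The epithelial list (the miR-200 family, miR-192, miR-194, miR-215, miR-203) had 8 of 9 members above 0, 1 of them higher when adjusted over the list alone, and a median of 0.61. The liver and pancreas list, in which miR-122 was not tested, had 4 of 4 tested members above 0 with a median of 0.56 (miR-375-3p, miR-216a-3p, miR-216a-5p and miR-217-5p). Neither passed, with camera adjusted p values of 0.144 and 0.216. The ieET-1 long term library 8135 held miR-192-5p at 13.3 on the log2 scale, where the next library of its group was at 10.4. In the endothelial list 1 of 5 members was lower when adjusted over the list alone, and 0 when adjusted over all miRNAs tested. The miR-15/16 family, which targets Vegfa mRNA, had 7 of 9 members above 0 and a median of 0.11 (camera adjusted p = 0.44). Within ranges of animal number limma called 0 miRNAs among the mice in the 8000s, with 47 at an unadjusted p below 0.05, and 0 among those in the 9000s, with 42. Both of these counts lie above the 17.7 that chance gives. Among the mice in the 9000s miR-221-5p had a log2 change of 0.037 and miR-187-3p of -0.42, both opposite to the change over all mice.

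A test of whether the genotype effect differed between the times called 0 miRNAs in limma, with 24 at an unadjusted p below 0.05 against 17.7 by chance, 0 in edgeR with 28 and 0 in DESeq2 with 36. miR-194-5p again had the smallest p among miRNAs with a more positive genotype effect at long term (2.73-fold), followed by miR-301b-3p (1.89-fold) and miR-183-5p (3.73-fold), and miR-27a-5p had the smallest p among those with a more negative one (0.438-fold), followed by miR-3068-3p (0.629-fold) and miR-3968 (-1.10 on the log2 scale). All had an adjusted p of 0.602. The interval of this difference lay within 2-fold for 145 of 354 miRNAs, fewer than in either single comparison. The striated and cardiac muscle list had 1 of 6 members above 0 and a median of -0.56 (camera adjusted p = 0.0934, or 0.38 with an estimated correlation). Its tested members include miR-486-3p and both rows of miR-486-5p, whose reads are shared. The miR-29 family, with 5 of 5 members above 0 (median 0.41), and the miR-181 family, with 1 of 6 (median -0.42), had the same camera adjusted p. Theirs was 0.549 with an estimated correlation. Averaged over both times, the genotype effect gave 0 calls in limma, with 5 miRNAs at an unadjusted p below 0.05, 0 calls in edgeR with 5 and 0 in DESeq2 with 3. The lowest p belonged to miR-143-5p, 1.33-fold higher in ieET-1 mice (adjusted p = 0.978), and the interval lay within 2-fold for 331 miRNAs (93.5%).

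In control mice, 12 of 42 tested miRNAs of the imprinted Dlk1-Dio3 cluster were lower at 3 months than at 16 days after tamoxifen, and as a list the cluster passed camera at a fixed correlation but not at an estimated one (adjusted p = 0.0798). miR-431-5p fell from 16.3 ± 6.95 to 3.40 ± 2.16 (SD, n = 7 each), a fold of 0.253 with a log2 change of -1.98 ± 0.33 (SE), miR-411-3p fell to 0.411 of its short-term level, miR-337-5p to 0.447 and miR-541-5p from 217 ± 124 to 93.0 ± 22.3 (0.474-fold). Outside the cluster, miR-138-5p fell from 32.2 ± 24.3 to 6.43 ± 4.92 (0.226-fold) and miR-872-3p to 0.438. Higher at 3 months were miR-143-3p (2.69-fold), miR-101a-3p (from 648 ± 146 to 1850 ± 1108, 2.54-fold), miR-10b-5p (2.48-fold), miR-19b-3p (2.40-fold), miR-582-3p (2.36-fold) and miR-101b-3p (2.21-fold). For each of these miRNAs 7 of 7 long-term mice lay on the side of the change from the short-term mean. They were named for their change in the same mice, so this follows in part from the choice. The 2 times differ in age and animal number as well as in time since tamoxifen.

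limma called 28 of 354 miRNAs in control mice, 8 higher and 20 lower, and edgeR on the recovered reads called 16 higher and 14 lower, with 7 and 13 called by both. DESeq2 called 24 higher and 29 lower. In the Dlk1-Dio3 list, 12 of 42 tested members were lower, 20 when adjusted over the list alone, and 39 had a negative change. The count was 5 of 32 among mice numbered 8000 or above and 35 of 42 scaled to the total of all miRNA reads. Under that scaling most of all miRNAs tested were called lower, as given below, so the higher count is not particular to this list. The median log2 change was -0.61, against -0.07 for the other miRNAs (camera adjusted p = 1.12e-08, or 0.0798 with an estimated correlation). The difference of these medians was -0.54, or -0.261 with a pseudocount of 5, -0.815 with edgeR and -0.907 over 14 members with the filter at 10. With fry, which tests whether the members move one way and does not compare them with other miRNAs, the adjusted p was 0.000137. Named members besides those above were miR-300-3p (0.507-fold, adjusted p = 0.00364) and miR-154-5p (0.485-fold, adjusted p = 0.0108). By name in GENCODE M21 (GRCm38), the 30 precursor genes of the list lie on chromosome 12 from 109571990 to 109743795, downstream of Meg3 and across Rian and Mirg. The Mir431 precursor, at 109590447 to 109590537, overlaps an exon of Rtl1 on the opposite strand, and Mir541, at 109742409 to 109742498, lies in an intron of Mirg. The genome build behind the deposited table is not given in the sources used here.

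Leukocyte, erythroid and adipose lists did not pass among all control mice (camera adjusted p = 0.709, 0.596 and 0.38), although the erythroid list had 3 of 3 members below 0 and a median of -0.76. In ieET-1 mice the erythroid median was -0.54 (camera adjusted p = 0.716). The smooth muscle list passed with fry (adjusted p = 0.0264) and not with camera (0.331). The higher value of miR-143-3p in control mice passed in 47 of 50 settings and depended on the scaling of the libraries. In ieET-1 mice its share of all miRNA reads was 52.8% ± 13.1 at long term against 42.0% ± 6.87 at short term. The exact permutation p (two-sided) was 0.0601, or 0.123 after adjustment over 8 library measures. In control mice the share was 48.6% ± 11.6 at long term against 38.0% ± 6.80 at short term. The exact permutation p was 0.0577, or 0.123 after the same adjustment. A share that starts at 38.0% cannot rise 2.69-fold, so it cannot show a change of that size. The normalization factor implied by the deposited values was 0.704 ± 0.251 at long term against 1.43 ± 0.353 at short term (exact permutation p = 0.00117, adjusted 0.00936). Scaled to the total of all miRNA reads, the median change of all miRNAs was -0.93 and limma called 213 miRNAs lower and 0 higher, and miR-143-3p (log2 change 0.34) and miR-10b-5p (0.22) did not pass. Relative to the other miRNAs the Dlk1-Dio3 median was then -0.44. Among mice numbered 8000 or above, 3 at short term and 7 at long term, limma called 15 higher and 18 lower, of which 14 were called in the same direction among all control mice. In those mice camera also passed the adipose and let-7 lists as higher and the miR-15/16 family as lower (adjusted p = 0.0225 each), and none of these passed with an estimated correlation (adjusted p = 0.51 each). Without ieCre long term 8149 the count was 18.

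In ieET-1 mice 8 of 42 Dlk1-Dio3 miRNAs were lower at 3 months, and the list again passed camera at a fixed correlation but not at an estimated one (adjusted p = 0.0596). miR-541-5p fell from 232 ± 103 to 78.3 ± 16.9 (SD, n = 8 each), 0.367-fold, miR-434-5p from 19.2 ± 2.01 to 7.99 ± 4.80 (0.399-fold), miR-431-5p to 0.447, miR-433-3p to 0.525, miR-668-3p to 0.543 and miR-411-3p to 0.562 of the short-term level. miR-215-5p rose from 2.18 ± 0.972 to 12.7 ± 13.1, a fold of 3.04. miR-182-5p (2.84-fold), miR-101a-3p (2.28-fold), miR-19b-3p (2.15-fold), miR-101b-3p (2.14-fold) and miR-29b-3p (1.75-fold) were also higher. Of these calls, miR-182-5p passed in 16 and miR-29b-3p in 19 of 50 settings, miR-19b-3p in 31, miR-101a-3p in 37 and miR-101b-3p in 46, and among the lower miRNAs miR-411-3p passed in 30 of 49. For each of the lower miRNAs 8 of 8 long-term mice lay below the short-term mean, and for miR-215-5p 7 of 8 and for miR-182-5p 6 of 8 lay above it. These miRNAs too were named for their change in the same mice.

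limma called 21 miRNAs in ieET-1 mice, 7 higher and 14 lower, and edgeR called 22 higher and 16 lower, with 5 and 13 called by both. DESeq2 called 29 higher and 18 lower. In the Dlk1-Dio3 list 8 of 42 members were lower, 10 when adjusted over the list alone, and the median was -0.52 (camera adjusted p = 2.76e-09, or 0.0596 with an estimated correlation, and 0.000386 with fry). The median minus that of the other miRNAs was -0.479, or -0.241 with a pseudocount of 5, -0.651 with edgeR and -0.676 over 14 members with the filter at 10. The count of 8 was 5 without any 1 of ieET-1 short term 257 or 258 or ieET-1 long term 8150 or 8151, 3 without the near-identical pair, 2 with thinned reads, 0 among mice numbered 8000 or above and 18 with array weights. The epithelial list had 9 of 9 members above 0, 1 of them called and 2 when adjusted over the list alone, with a median of 1.13 (camera adjusted p = 0.00154, or an adjusted p of 0.489 with an estimated correlation). The liver and pancreas list moved the same way, with 4 of 4 members above 0 and a median of 0.94, without passing (camera adjusted p = 0.114). miR-192-5p was at 2.39-fold without passing, and for miR-429-3p, which did not pass either, 4 of 8 long-term mice lay above the short-term mean. The list of the miR-29 family, which targets collagen mRNAs, names 3 miRNAs and takes both arms of each. It had 5 of 5 tested members above 0 and 1 called, also 1 when adjusted over the list alone, with a median of 0.38 (camera adjusted p = 0.032, or an adjusted p of 0.489 with an estimated correlation). Scaled to the total of all miRNA reads, where the median of all miRNAs was -0.47, miR-29a-3p (-0.13) and miR-29c-3p (-0.081) were below 0 but above that median. Libraries 8135 and 9490 were the highest of the ieET-1 long term group in the miR-200 family. Without these 2 libraries the camera adjusted p was 0.192 for the epithelial list, 0.192 for the miR-29 family and 1.09e-05 for the Dlk1-Dio3 list. The 2 libraries were chosen for high values of members of the epithelial list, so its weaker result follows in part from the choice. Library 9490 was also the highest of the group in miR-29a-3p, miR-29b-3p and miR-29c-3p.

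The count in ieET-1 mice depended on single libraries. It was 7 without both near-identical libraries and 0 among mice numbered 8000 or above, where 30 had an unadjusted p below 0.05 and the smallest adjusted p was 0.0528. The count was 10 without ieET-1 long term 8134, 12 without 8150, 10 without 8151 and 11 without 8152, and 10 without ieET-1 short term 255, 13 without 256, 11 without 257 and 11 without 258. With array weights it was 97. Among mice numbered 8000 or above, the 42 members of the Dlk1-Dio3 list had a median of -0.52 in ieET-1 mice (camera adjusted p = 4.28e-09, or 0.0286 with an estimated correlation) and of -0.27 in ieCre mice (0.0225, or 0.51 with an estimated correlation). In the ieET-1 mice of that range camera also passed the erythroid and the striated and cardiac muscle lists as lower and the let-7, epithelial and miR-29 lists as higher, and none of these passed with an estimated correlation (adjusted p = 0.439 each).

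**Figure D2:**
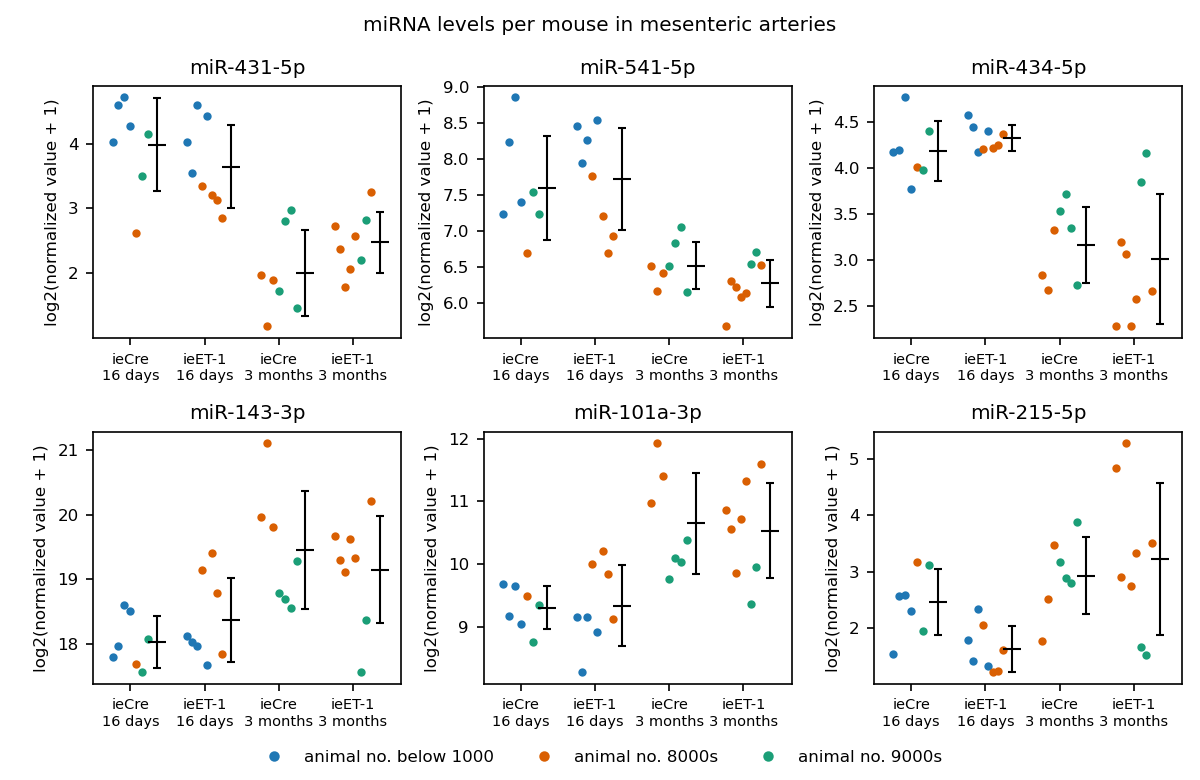
Values of 6 miRNAs in each mouse, as log2 of the deposited normalized value plus 1 (y axis), in the 4 groups (x axis); points are mice coloured by the range of their animal number, and the bars give the mean and SD of each group. The Dlk1-Dio3 miRNAs miR-431-5p, miR-541-5p and miR-434-5p have lower means at 3 months in both genotypes, and miR-143-3p, miR-101a-3p and miR-215-5p have higher means.

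Of the miRNAs called in the 2 genotypes, 3 of those higher were shared (miR-101a-3p, miR-101b-3p and miR-19b-3p), where independent lists give 0.158, and 9 of those lower, where independent lists give 0.791. The shared lower miRNAs were miR-431-5p, miR-541-5p, miR-434-5p, miR-433-3p, miR-300-3p, miR-411-3p, miR-668-3p, miR-449a-5p and miR-125b-1-3p. The last 2 fall outside the naming rule and were chosen after their values were seen. Without the near-identical pair, which lies in both short-term groups, 1 higher and 4 lower miRNAs were shared. Both short-term groups also hold mice numbered below 1000 and no long-term group does, so the 2 lists are not independent. Of the calls over time, 8 in ieCre and 5 in ieET-1 mice were also called in the same direction between the ranges of animal number at short term. The sharing therefore does not separate time from animal number. Across 354 miRNAs, which are not independent replicates, the changes of the 2 genotypes had a Pearson correlation of 0.518, or 0.439 without the pair. The interaction test above called 0 miRNAs, so no difference between the genotypes in the change with time was detectable.

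**Figure D3:**
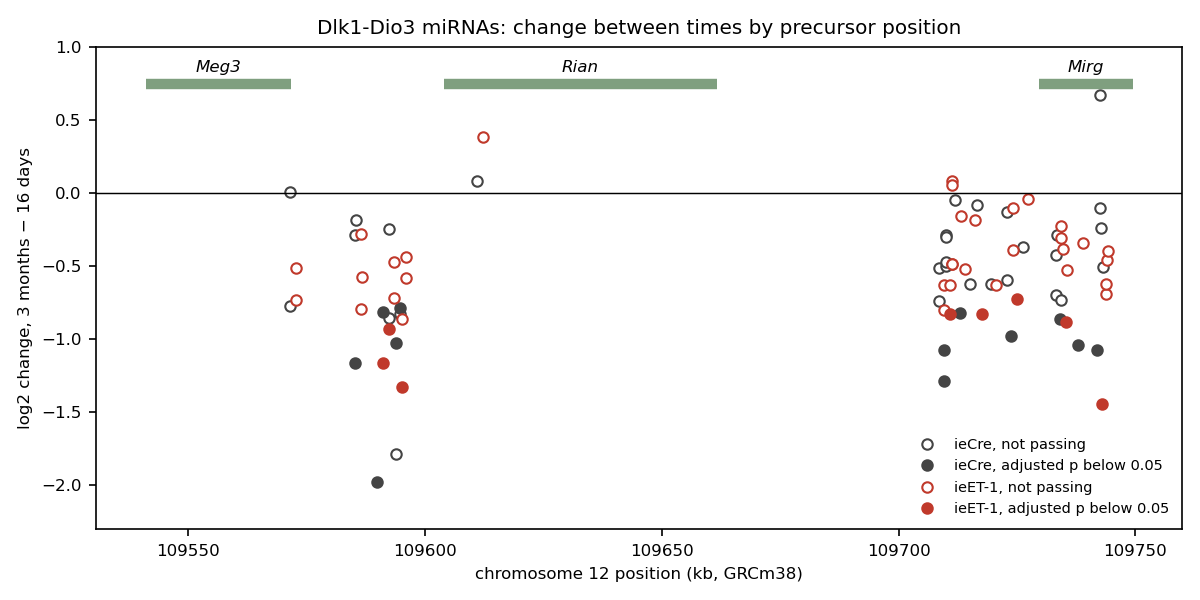
Log2 change from 16 days to 3 months (y axis) of the tested Dlk1-Dio3 miRNAs against the position of their precursor on chromosome 12 in kb, GRCm38 (x axis), in ieCre and ieET-1 mice; filled points passed an adjusted p of 0.05 and green bars mark Meg3, Rian and Mirg. The points of the 2 genotypes are drawn side by side, and 39 of 42 miRNAs lie below 0 in each genotype.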

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

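For the named miRNAs and library measures, a mouse lay far from the rest of its group, by its gap to the nearest mouse relative to the range of the group, in 15 of 220 cases tested, where chance gives 11. They are given as log2 values. In ieET-1 long term 8134, miR-423-3p (0.768), miR-196b-5p (3.73) and miR-19a-3p (0.434) were the lowest of the group. In ieET-1 long term 8136, miR-18a-5p was listed at 0. In ieET-1 long term 8151, miR-433-3p was lowest at 0.191. In ieET-1 long term 8135, miR-192-5p (13.3, next 10.4) and miR-31-5p (4.27, next 2.20) were the highest. In ieET-1 long term 9490, miR-29a-3p (9.30), miR-29b-3p (5.47) and miR-29c-3p (6.97) were the highest. In ieET-1 short term 257, miR-429-3p was highest at 2.43. In ieCre long term 9491, miR-187-3p was highest at 2.28 and miR-221-5p lowest at 0.433, and both miRNAs are among those named for the long-term genotype comparison. In ieCre short term 10, miR-154-5p was highest at 3.12, and in ieCre short term 9957, with the fewest reads, miR-339-3p was lowest at 0.971.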

How the results depend on the processing

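The genotype counts at short term, long term, averaged and in the interaction were 0 under each alternative run, planned or added. Libraries left out one at a time gave 18 to 39 changed miRNAs in ieCre mice over time and 10 to 31 in ieET-1 mice. In ieET-1 mice over time (21 miRNAs) the count was 12 with a filter at 10, 11 with quantile scaling, 97 with array weights and 38 with edgeR. With alternatives chosen after seeing the data it was 7 without the near-identical pair (12 with edgeR), 6 without libraries under 5000000 reads, 8 with log2 reads as a term, 3 with thinned reads, 0 among mice numbered 8000 or above and 47 with DESeq2. In ieCre mice (28 miRNAs) it was 53 with DESeq2 and 213 scaled to all miRNA reads, where it was 18 in ieET-1 mice. Fewer mice or reads enter several of these fits, and for the others the cause was not tested.

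The split of higher and lower miRNAs in ieCre mice was 14 and 20 with median-ratio and 16 and 16 with TMM scaling, and in ieET-1 mice 6 and 6 with the filter at 10. Lists passing in ieCre mice over time (1) numbered 0 with an estimated correlation, 2 with fry and 4 among mice numbered 8000 or above, or 0 there with an estimated correlation. In ieET-1 mice (3) they numbered 0, 1 and 6, or 1 there with an estimated correlation, and 1 without the 2 libraries with high miR-200. Leaving out libraries for high miR-200 lowers the epithelial list in part by that choice. Scaled to all miRNA reads in ieET-1 mice, miR-29c-3p (-0.0812) and miR-29a-3p (-0.133) fell below 0 with a shift common to all miRNAs (median -0.47), above which both stayed. The change reversed for miR-196b-5p (-0.089) at short term among mice below 1000, and for miR-187-3p (-0.42) and miR-221-5p (0.0368) at long term among mice in the 9000s. Quantile scaling fixes miR-143-3p and miR-10b-5p at their ranks, so that they show no change there. Depth limits miRNAs near the filter, which stands for as few as 3 reads in some libraries.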

Other observations

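Averaged over both genotypes, a comparison added after the data were seen, 30 miRNAs were higher and 48 lower at 3 months than at 16 days (limma, 354 tested), and 19 of the 48 belonged to the Dlk1-Dio3 cluster. Beside the miRNAs of the report these included miR-127-3p of that cluster (0.579-fold, adjusted p = 0.00427), miR-22-3p (0.624-fold, adjusted p = 0.00265) and miR-191-5p (0.635-fold, adjusted p = 0.0108), all chosen after their values were seen. Higher were miR-23b-3p (1.42-fold, adjusted p = 0.00303), miR-340-5p (1.68-fold, adjusted p = 0.0108) and miR-9-5p (1.97-fold, adjusted p = 0.0108). Among mice numbered 8000 or above 18 were higher and 25 lower, and 26 of these were called in the same direction over all mice. In that range 10 of the lower miRNAs belonged to the Dlk1-Dio3 cluster, and miR-340-5p (adjusted p = 0.061) and miR-9-5p (0.118) did not pass. Without the near-identical pair 19 were higher and 38 lower.

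The tests in the next 3 paragraphs were chosen after the results were seen, and the comparisons with other splits of the mice before. The near-identical counts of ieCre short term 8 and ieET-1 short term 258 are consistent with 1 set of reads entered under 2 labels: 0 miRNAs had more reads in the smaller library. Separate libraries made from 1 RNA are argued against, since 1000 binomial draws from 1 pool gave at least 111 such miRNAs, and 64 other pairs with similar totals gave at least 38. Which genotype the reads belong to stays open, and no biological explanation was tested.

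The lower Dlk1-Dio3 miRNAs at 3 months were weighed against depth, scaling and animal number, with the list's median log2 change minus that of the other miRNAs. With reads thinned to 1 depth it was -0.51 in the genotype nearer 0, and at or below -0.36 with any library left out. This argues against depth as the whole cause. Over 6 scalings it was -0.44 at the nearest to 0, and at or below -0.34 with any library left out. A factor common to all miRNAs of a library largely cancels in this measure, so these values are no test of such factors. Quantile scaling, which is not such a factor, gave -0.509 in ieCre and -0.445 in ieET-1 mice. Among mice numbered 8000 or above the difference was -0.32, or -0.23 with 1 library left out, with the filter of all mice. With the filter redone, which leaves 32 members, it was -0.51 in ieCre and -0.575 in ieET-1 mice. Among short-term mice 12 members of the list were lower and 3 higher in the range at 8000 or above than below 1000. A cohort effect marked by animal number may therefore account for part of the change and cannot be told apart from it with 3 ieCre and 4 ieET-1 short-term mice in that range, and age and time since tamoxifen stay open and untested.

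For the 2.69-fold higher miR-143-3p in ieCre mice at 3 months, the scaling of the libraries stays a candidate explanation that the share of reads cannot decide. As a share of all miRNA reads the fold was 1.27 (exact permutation p = 0.0664 on the log2 scale). A miRNA that took 38.0% of the reads at short term cannot rise 2.69-fold as a share. A small fold of the share therefore does not separate scaling from a real rise. The rise does not rest on the mice numbered below 1000 alone. Its fold was 3.2 among mice numbered 8000 or above (7 long-term and 3 short-term mice) and at least 2.64 with any of them left out. In these 3 short-term mice (8754, 9955 and 9957) the share was 35.2%, 27.9% and 31.9%, against a long-term mean of 48.6% ± 11.6. The long-term shares were 54.32%, 66.41% and 56.45% in the 8000s and 33.55%, 43.45%, 36.66% and 49.59% in the 9000s. Too few short-term mice lie in each of these ranges to match animal number between the times, so it stays open as a cause. Scaling and animal number were not tested together. A change in miR-143-3p itself stays open.

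In 100 splits of the mice, the real one included, 1 split (the real one) called as many as the 28 miRNAs over time in ieCre mice, with at most 1 in any other. In ieET-1 mice 1 called as many as the 21, with at most 8 in any other. Chance alone is argued against for both but not excluded, since the splits number only 100 and ignore animal number. The 8 mice numbered below 1000 are all short term, so these splits do not separate time from animal number, and the 21 in ieET-1 mice were 7 without the near-identical pair and 0 among mice numbered 8000 or above. For the genotype comparisons and the interaction the real count was 0, so all 100 splits had to call as many, and this comparison decides nothing about chance. The highest other splits called 28 at short term, 16 at long term, 2 for the interaction and 4 averaged. The short-term split with 28 calls placed 7 of 7 mice of 1 group and 1 of 8 of the other in the range below 1000, which points to a structure of the samples by animal number.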
